A study of Mus musculus with 16 samples.

How the data were processed

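ATAC-seq libraries of sorted mouse CD8 T cells were compared at the level of accessible regions. Samples were grouped by their labels. The 3 PD1hi libraries from mice given the anti-IL-10R antibody were compared with the 3 PD1hi libraries from mice given the isotype antibody, and the samples of other subsets were not analysed here. The column heads of the deposited table call the antibody libraries "IL10r KO", while the sample labels describe a blocking antibody given to randomised mice. The libraries are described here as antibody-treated, as the sample labels have it.

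Per the submitters' processing notes, the tools were Trimmomatic 0.36, SAMtools 1.3, Picard, DiffBind and DESeq2, and the genome build was mm9. The aligner, the peak caller, the read shift and the handling of duplicates and of mitochondrial reads were not given in the sources used here. Per the file headers, the authors' deposited table holds for each region its position, a mean signal, a fold change and its error, a test score, a p-value and an adjusted p-value, and 1 value for each of the 6 libraries. The deposited signal is the mean over the 6 libraries of reads normalised by the authors. The deposited log2 fold changes are antibody over isotype, with the authors' standard errors, and the deposited score is their ratio within rounding. The authors' adjusted p-value is absent for 66582 regions of low signal, and the lowest mean with an adjusted p-value is 5.76 normalised reads. The deposited per-library values are on a log2 scale, normalised by the authors by a transformation that the sources used here do not name. They run from -0.03 to 12.2, and differences between arm means are smaller than the deposited log2 fold changes, most of all at low signal, so they are shrunk. A difference of these values therefore understates the change in reads on average. Deposited region starts counted from 0, and 1 was added to give positions as a genome browser shows them.

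The table gives no read counts per library. Relative depth here is the factor by which the authors' normalisation scaled a library. It was read from the steps of the mean signal among the weakest regions, where a single library exceeds the others by whole reads. A straight-line fit was made per library over 271 to 730 regions. The depth of a library in reads is unknown, and no counting interval is given.

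The plan made before the data were examined foresaw limma on the log2 of normalised values with a small number added. Since the deposited values were already on a log2 scale, limma 3.58.1 (R 4.3.3) was run on them directly, with nothing added, with 1 prior variance for all regions, 3 libraries against 3 and no covariate. The prior had 2.53 degrees of freedom beside 4 residual ones. P-values were adjusted by Benjamini-Hochberg over the 190778 regions, with a threshold of 0.05. Regions were named by a rule set before the data were examined: the 8 gained and 8 lost regions with the lowest adjusted p, ties going to the larger difference. The 5 loci named per direction are those with the most called regions, a rule added after the data were examined, as were the locus definition (gap of 20 kb) and the restriction of loci and signal classes to autosomes. Shuffles kept chromosome and 10 classes of mean signal. The share of neighbours called the same way and the size of a region's locus were matched on 10 classes of the region's own signal and on its number of neighbours within 20 kb in signal class 4 or 5, and intervals came from 1000 bootstrap draws of the autosomes. Such intervals hold no variation between mice. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and version 1.17.8 of the R package data.table.

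The limma step was tested on simulated data with the layout of the comparison of antibody with isotype PD1hi cells over 190778 regions. Errors were drawn as independent normal values from the fitted prior variance, and changes were placed only in regions above the median signal. The simulation therefore checks the fit under its own assumptions and gives no rate of recovery for weaker regions. With 200 regions changed, 52% of those changed by 1 on the log2 scale and 0% of those changed by 0.5 were called, and 5 of 57 calls (8.8%) were false. With 20000 regions changed, 95% and 76.8% were called, and 4.3% of the calls were false. The neighbour test gave 0.956 times the shuffled number of like pairs for random calls over 184387 autosomal regions.

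Gene names, 15 planned gene lists, positions relative to promoters and sequence motifs need an annotation or sequence of mm9, which was not used here, so these planned analyses and their alternatives were not run and regions are given by position only. Markers of other cell types could not be examined for the same reason. The comparisons between CD8 subsets were not run, as their libraries were not analysed here. Alternatives tried were quantile and cyclic loess normalisation, a filter on low signal, other thresholds, another adjustment, a trended prior, leaving out each library, a block for the replicate number, leaving out chromosome X, merging of near regions, other gaps between regions of a locus, and the authors' deposited p-values in place of limma.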

Results

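Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA so that the number of reads over a region reflects how accessible it is. The cells were CD8 T cells sorted from the spleens of C57BL/6 mice that had received splenocytes from leukaemic TCL1 mice, a transgenic model of chronic lymphocytic leukaemia. The recipients were then randomised to an antibody that blocks the receptor of interleukin 10, a cytokine that restrains immune responses, or to an isotype control antibody, with 3 mice per arm. The labels describe 16 samples in 6 groups. These are 3 antibody and 3 isotype samples of PD1hi effector cells, 3 isotype samples each of PD1int effector and memory cells, 1 isotype sample of naive cells, and 3 samples of naive cells from mice without tumour. PD1hi cells were CD127-negative and CD44-positive with high surface PD-1, an inhibitory receptor that stays high on T cells under lasting stimulation. The values analysed cover the 6 PD1hi libraries. The other subsets were not analysed here, so each comparison below is between the arms within PD1hi cells.

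The 190778 accessible regions had a median width of 232 bp and a median of 10.4 mean normalised reads per library, from 0.98 to 4492.2. Summed over regions, the authors' mean normalised reads came to 11761656 per library. Relative depths read from the steps between the lowest values were 1.01, 0.992 and 1.02 for antibody replicates 1, 2 and 3. They were 1.10, 1.01 and 1.00 for isotype replicates 1, 2 and 3, so depth differed little between the arms. Absolute depth per library was not given in the sources used here. On the autosomes, Pearson's r across regions was 0.996 to 0.997 between libraries of the same arm and 0.992 to 0.994 between libraries of different arms. These are correlations across regions, which are not independent replicates. The first principal component held 53.9% of the variance and separated the arms, with antibody libraries at 39.1 to 59.2 and isotype libraries at -56 to -41.

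The first question was which regions of PD1hi cells open or close when the IL-10 receptor is blocked. Accessibility rose at 6263 regions and fell at 6538, together 12801 of 190778 or 6.71% (limma, Benjamini-Hochberg adjusted at 0.05, 3 libraries against 3). The 8 gains and the 8 losses with the lowest adjusted p each lay on 6 chromosomes, and 3 of those losses lay within 33.9 kb on chromosome 17. Of the 6263 gains, 75 lay on chromosome X, where isotype replicate 2 had much lower signal than the other libraries. Without that chromosome, the refitted autosomes gave 14025 changed regions, 6763 gained and 7262 lost. The count depended on which libraries were used: it was 3743, 6736 and 8252 without antibody replicate 1, 2 or 3, and 4001, 5617 and 6364 without isotype replicate 1, 2 or 3, and gains were 49.2 to 58.1% of the calls in these fits. In the authors' deposited table, 15551 regions passed an adjusted p of 0.05, of which 7325 were higher and 8226 lower under the antibody. Of the limma calls, 10422 (81.4%) passed that threshold in the authors' deposited table as well, and those shared calls had the same direction. A further 5129 regions passed the authors' threshold and were not called by limma. Both sets of calls come from the same 6 libraries, so a shared direction is no independent support.

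Among the 8 named gains, whose adjusted p was the same as rounded, the region with the largest difference lay on chromosome 2 from 106845626 to 106846420 (mm9, as all coordinates here). Its log2-scale signal was 7.11 ± 0.17 (SD, n = 3) under the antibody and 4.79 ± 0.04 (SD, n = 3) under the isotype control, a limma difference of 2.32 with an SE of 0.09. A second region of chromosome 2, from 130919101 to 130919726, had 6.48 ± 0.09 against 4.35 ± 0.08 (SD, n = 3 each). The region on chromosome 11 from 68519973 to 68520602 had 6.24 ± 0.10 against 4.12 ± 0.13 (SD, n = 3 each). On chromosome 1, the region from 180634155 to 180634901 stood at 6.80 ± 0.11 against 4.72 ± 0.12 (SD, n = 3 each). The other 4 were on chromosome 10 from 82137675 to 82138339, on chromosome 7 from 118923337 to 118923853, and on chromosome 6 from 30309778 to 30310470 and from 136963002 to 136963539. Their limma differences were 2.07, 2.06, 1.78 and 1.64 in that order. Each of the 16 regions named here and in the next paragraph had a limma adjusted p of 2.1e-03. The per-library values are shrunk toward each region's mean, so these differences understate the change. The authors' deposited table gives a log2 fold change of 4.22 with an SE of 0.31 for the first region. Over the 8 gained regions the log2 fold changes in the authors' deposited table ran from 3.10 on chromosome 6 to 4.88 on chromosomes 7 and 11.

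Among losses, the region on chromosome 17 from 47362794 to 47362980 had 4.14 ± 0.05 under the antibody and 5.60 ± 0.08 under the isotype control (SD, n = 3 each). An adjoining region, from 47362132 to 47362695, had 5.23 ± 0.16 against 7.12 ± 0.04, and one from 47329124 to 47329635 had 5.21 ± 0.13 against 6.97 ± 0.10 (SD, n = 3 each). On chromosome 10, the region from 19796647 to 19797636 fell by 2.26 (limma SE 0.11), from 7.64 ± 0.04 to 5.38 ± 0.22 (SD, n = 3 each). In the authors' deposited table that region has a log2 fold change of -3.65 with an SE of 0.23 and the rank 2 of all regions by adjusted p. The region on chromosome 2 from 103570818 to 103571425 fell by 1.58, and the region on chromosome 7 from 139995514 to 139996005 fell by 1.28. On chromosome 14 the region from 63488935 to 63489705 fell by 1.22, and on chromosome 11 the region from 103242794 to 103244047 fell by 1.20. The last was the strongest of the 16 in signal, at 231.9 mean normalised reads. In the authors' deposited table the 8 lost regions range in log2 fold change from -3.65 to -1.73.

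**Figure D1:**
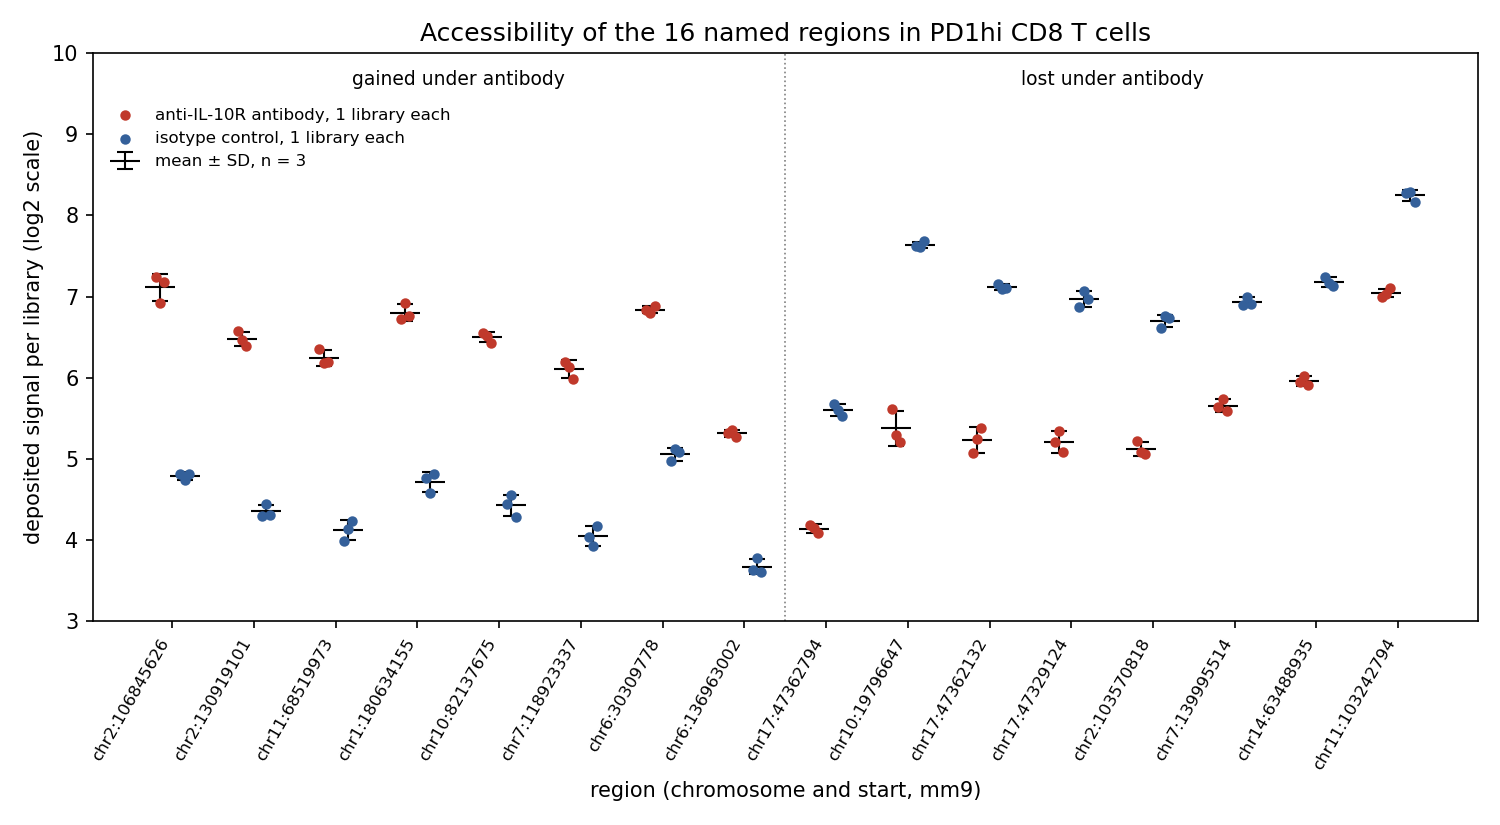
Deposited log2-scale signal of each PD1hi library at the 8 gained and 8 lost regions with the lowest limma adjusted p, with the group mean ± SD (n = 3). The libraries of the 2 arms do not overlap at any of the 16 regions, as follows from choosing them by the test.

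The second question was whether changed regions lie alone or side by side, and it was asked after the data were examined. Autosomal regions called in 1 direction and at most 20 kb from the next such region, with no opposite call between them, were joined into a locus. Signal classes are 5 equal classes of autosomal regions by mean normalised reads, 1 the weakest and 5 the strongest. The 6188 autosomal gains formed 4447 loci and the 6538 losses formed 3463 loci, or 1.39 regions per gained locus and 1.89 per lost locus. When the direction was shuffled among called regions within chromosome and 10 classes of signal, the highest of 1000 shuffles gave 1.25 for gains and 1.31 for losses. Nearby called regions thus shared a direction more often than shuffled ones. This shuffle kept the called positions, so it does not show whether changed regions lie alone or side by side. Losses also lay where regions were denser: called regions with any neighbour of signal class 4 or 5 within 20 kb had on average 7.24 such neighbours if lost and 3.32 if gained. The share of these neighbours called the same way was lower for losses, 24.2% against 29.7% for gains, and 21.9% against 24.97% when matched on signal and on the number of neighbours. The locus of a lost region held on average 2.26 more regions than that of a gained region (95% bootstrap interval over chromosomes 1.84 to 2.72), and 0.82 more after the same matching (0.52 to 1.15). Loci with 5 or more regions held 1745 losses (26.7%) in 221 loci and 424 gains (6.85%) in 71 loci. Among calls that also differed by at least 1 on the shrunk scale, there were 1.19 regions per gained locus and 1.22 per lost locus. Next to a called region, the following region within 20 kb was called the same way in 23.1% of pairs and the opposite way in 0.498%. When calls were instead shuffled over all autosomal regions, within chromosome and 10 classes of signal, the shares were 4.52% and 4.34% on average (one-sided permutation p = 0.001 for both, the smallest that 1000 shuffles can give). This p holds no variation between mice. The shuffle treats each region as separate, though some neighbours lie within 500 bp of each other and may be parts of 1 accessible site. The shares after merging such regions are not given here.

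The lost locus with the most regions was the one on chromosome 17, from 47258898 to 47370165, 111.3 kb long. It held 40 lost regions, and their mean log2-scale signal was 4.52 ± 0.04 under the antibody and 5.53 ± 0.01 under the isotype control (SD, n = 3 each). In the authors' deposited table the log2 fold change was below 0 at all 44 regions of this span, with a median of -2.70 over the 40 called. The strongest regions of the span changed less. The strongest, at 768.6 mean normalised reads, had -0.21 and was not called. The next, at 437.5 reads, had -0.41. A locus of 114.9 kb on chromosome 10, from 39140607 to 39255523, held 34 lost regions, and all 59 regions of its span were below 0 in the authors' deposited table. Further loci lay on chromosome 13 from 24686123 to 24749050 with 21 lost regions, on chromosome 6 from 31029648 to 31134140 with 21, and on chromosome 5 from 112643325 to 112748724 with 20. Their median log2 fold changes in the authors' deposited table were -1.15, -1.03 and -1.03.

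Gained loci were smaller. The one with the most regions lay on chromosome 14 from 101852172 to 101915649, 63.5 kb long, and held 14 gained regions. Their mean log2-scale signal was 6.91 ± 0.03 under the antibody and 5.90 ± 0.10 under the isotype control (SD, n = 3 each). In the authors' deposited table all 17 regions of this span had a log2 fold change above 0, with a median of 1.57 over the 14 called. Loci of 10 gained regions lay on chromosome 5 from 53781248 to 53839687 and on chromosome 2 from 6477968 to 6525982. Loci of 9 lay on chromosome 2 from 38192090 to 38235060 and on chromosome 9 from 114667281 to 114704286. The means over a lost or gained locus are over regions already called. Most of the regions counted by sign in the spans above were also called, from the same libraries. Both therefore describe the loci and do not test them anew.

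**Figure D2:**
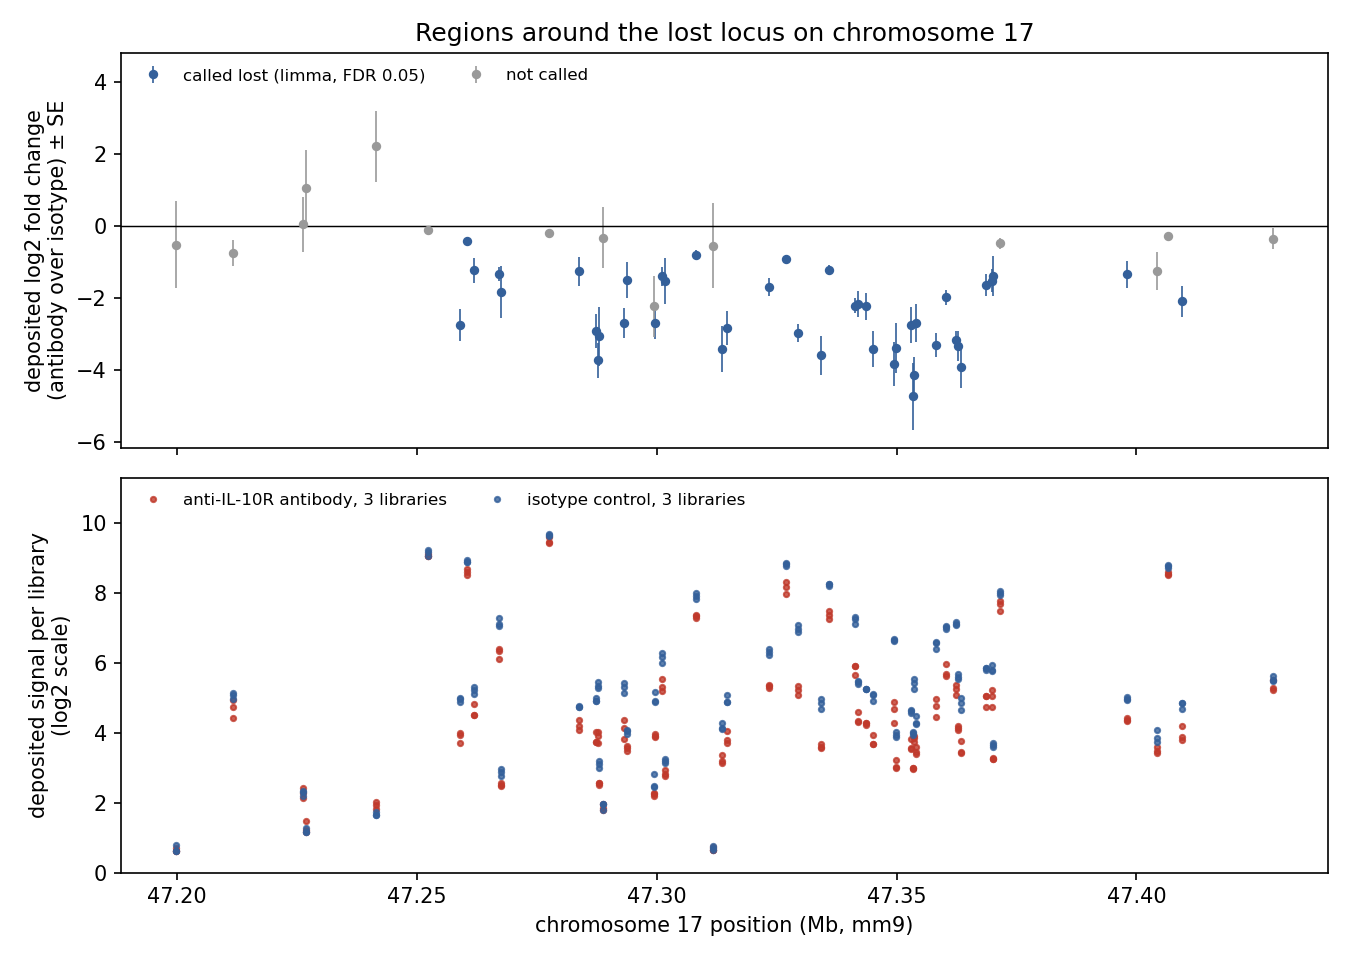
Regions around the lost locus on chromosome 17 (position in Mb, mm9). The upper panel shows the log2 fold change (antibody over isotype) ± SE from the authors' deposited table, and the lower panel the log2-scale signal of each of the 6 libraries. Lost regions lie side by side over 111.3 kb, with a median log2 fold change of -2.70 over the 40 called in this span. The strongest region of the span, at 768.6 mean normalised reads, has -0.21 and was not called.

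Gained and lost regions differed in signal and size of change. Autosomal gains had a median of 34.9 mean normalised reads and a median width of 502 bp, and autosomal losses 54.7 reads and 431 bp. The median log2 fold change in the authors' deposited table was 1.42 over the gains and -1.01 over the losses. It reached a size of 2 or more at 1546 of 6188 gained regions and 475 of 6538 lost regions in the authors' deposited table. Within equal classes of signal the gap was narrower: in class 5, the strongest, the medians in the authors' deposited table were 0.92 and -0.74, and in class 4 they were 1.42 and -1.16. The median over all regions was -0.11 in each of these classes. The narrower gap therefore cannot be told apart from a shift of the whole class. Across the 5 classes of mean signal, gains outnumbered losses 1362 to 663 in class 3 and losses outnumbered gains 2961 to 1891 in class 5. This contrast depended on the scaling. In classes 1 to 3 together gains were 69.5% of calls, and 60.6% after cyclic loess normalisation, which removes signal-dependent differences between libraries. In classes 4 and 5 together they were 43.6% of calls, and 56.3% after cyclic loess, so the excess of losses there turned into an excess of gains. Mean log2-scale signal in class 1 was 1.16, 1.16 and 1.13 in antibody replicates 1, 2 and 3, and 1.12, 1.13 and 1.13 in isotype replicates 1, 2 and 3. In class 5 it was 7.52, 7.52 and 7.60 in the antibody replicates and 7.62, 7.62 and 7.59 in the isotype replicates.

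**Figure D3:**
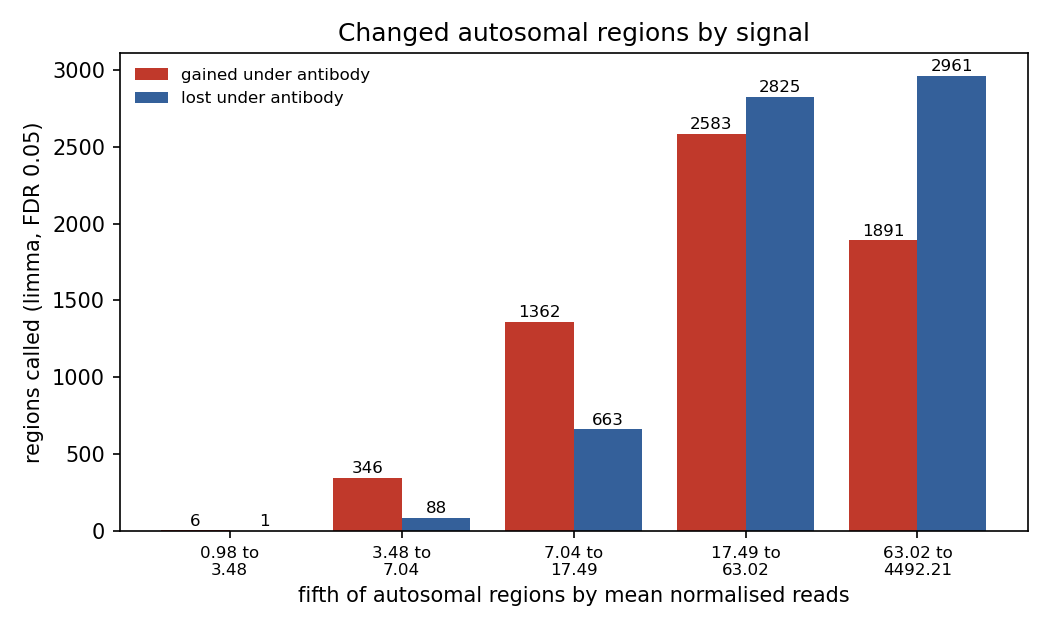
Number of autosomal regions gained (red) and lost (blue) under the antibody (limma, FDR 0.05) in 5 classes of mean normalised reads, weakest at the left. Gains outnumber losses 1362 to 663 in class 3, and losses outnumber gains 2961 to 1891 in class 5.

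Chromosome X stood apart. All 75 changed regions among its 6391 were gains and 0 were losses by limma, and at an unadjusted p of 0.05 the counts were 643 and 0. The authors' deposited table likewise has 100 regions higher and 0 lower on this chromosome at an adjusted p of 0.05. In the 787 X regions with at least 61.7 mean normalised reads, the median log2-scale signal was 5.08 in isotype replicate 2 and 7.57 to 7.71 in the other 5 libraries. With isotype replicate 2 left out and the adjustment made over all regions, limma called 62 gains and 24 losses on X, and 33 of the 75 earlier calls were among them. Adjusted over X alone, the same 5 libraries gave 0 gains and 0 losses by limma, with 467 and 379 at an unadjusted p of 0.05. No direction on chromosome X is therefore claimed, though the count of 6263 gains over all regions includes these 75. The loci and signal classes above are autosomal.

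**Figure D4:**
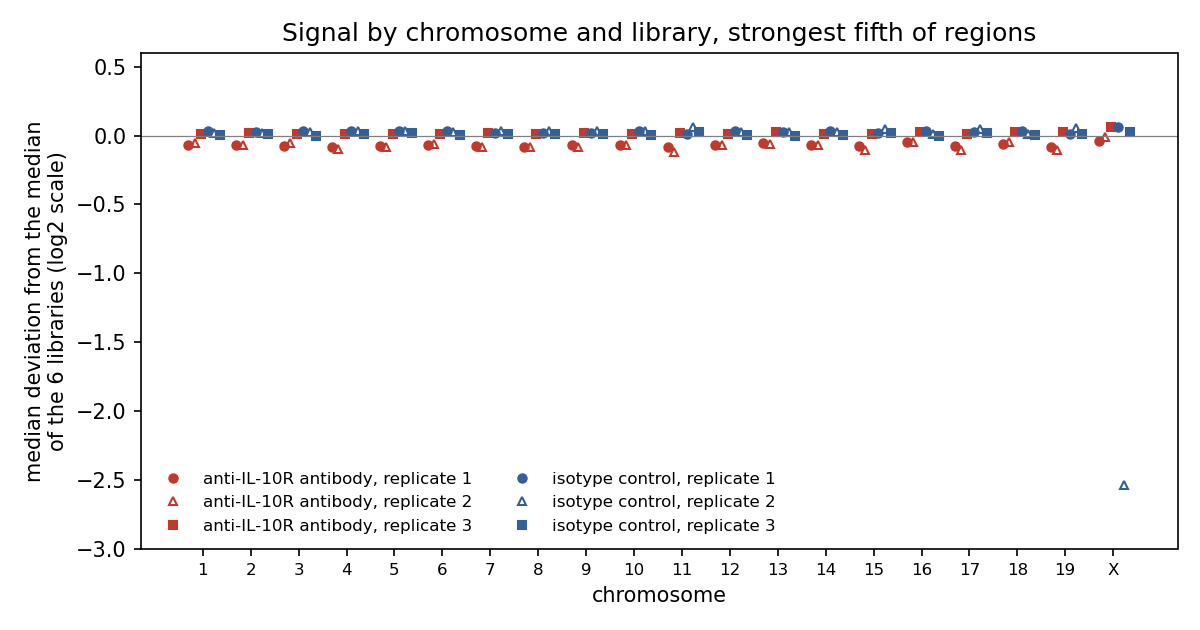
Median deviation of each PD1hi library from the median of the 6 libraries, per chromosome, over regions with at least 61.7 mean normalised reads (log2 scale). Isotype replicate 2 lies at -2.54 on chromosome X, and the other points lie between -0.12 and 0.065.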

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

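The prior trend, cyclic loess, the 10 kb and 50 kb gaps, the use of the deposited p-values and the joint removal of chromosome X and isotype replicate 2 were chosen after the data were examined. Leaving out chromosome X, either scaling, a filter or an adjustment without the 25% of regions lowest in signal, the trended prior, merging within 500 bp and either use of the authors' p-values kept the count of changed regions within 1.5 times of 12801, from 11721 with merging to 15903 with the adjustment over the regions above those 25%. The balance of directions was not stable: gains were 48.9% of calls (6263 against 6538 losses), 57.4% after cyclic loess (7492 and 5565) and 50.2% after quantile normalisation (6211 and 6156). They were 54.3, 49.2 and 51.7% without antibody replicate 1, 2 or 3, and 58.1, 55.7 and 49.4% without isotype replicate 1, 2 or 3. Leaving out 1 library at a time gave 3743 to 8252 changed regions, 2031 to 4269 gained and 1677 to 3983 lost, and leaving out chromosome X and isotype replicate 2 together gave 5768, 3193 and 2575. These settings use fewer libraries, which lowers the number of calls by construction, and why the counts differ between libraries was not tested. An FDR of 0.01 gave 2678 changed regions, 1540 gained and 1138 lost, and an FDR of 0.1 gave 21800, 10387 and 11413. Requiring also a difference of at least 1 on the shrunk scale left 981 regions, 686 gained and 295 lost, with 1.22 regions per lost locus in place of 1.89 and 1.19 per gained locus in place of 1.39, a gap of 0.04 in place of 0.496 (95% bootstrap interval -0.072 to 0.211). With the replicate block, 4527 regions were called, 2502 gained and 2025 lost. Libraries of the same number did not deviate together (r across autosomal regions of -0.043, -0.036 and -0.067 for numbers 1, 2 and 3), and no library correlated best with its own number. The deviations were taken from the mean of each arm and all these correlations were small, so a pairing by number was not seen but cannot be excluded. The value of regions per locus was higher for losses than for gains in each setting, though with that minimum difference the interval of the gap includes 0. The 16 named regions kept their direction and an adjusted p under 0.05 in all 256 comparisons with alternatives, the highest adjusted p being 0.029. They were chosen for the lowest adjusted p in the same 6 libraries, so this is close to fixed in advance and is no independent support. A pseudocount was not varied, since none was added, and count-based tools were not run for want of read counts. The alternatives planned for gene lists, positions and motifs were not run. Weak regions limit what can be seen: 7 of 36878 autosomal regions in the weakest signal class were called, against 4852 of 36878 in the strongest.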

Other observations

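The cyclic loess share and the order of the isotype libraries were set before their results were seen, and the other tests in this part were chosen after. Shuffles of direction, set beforehand for the size of lost loci, are not used here because they break up runs of calls in both directions.

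Gains and losses were spread unevenly over the autosomes. Counted as loci, 56.2% of 7910 changed loci were gains. Chromosome 18 had 179 gained and 84 lost loci (68.1% gains, adjusted p = 0.0016), chromosome 13 had 242 and 138 (63.7%, adjusted p = 0.013) and chromosome 2 had 418 and 244 (63.1%, adjusted p = 0.0016). Chromosome 15 had 154 gained and 178 lost loci (46.4% gains, adjusted p = 0.0018), and chromosome 17, which holds the lost locus with the most regions, had 175 and 178 (49.6%, adjusted p = 0.027). An adjusted p under 0.05 was also found for chromosomes 4, 5 and 11 (50.2, 50.3 and 50.3% gains) and for chromosome 16 (62.9%). These are Fisher's exact tests (two-sided, Benjamini-Hochberg over 19 chromosomes) across loci, which are not independent replicates. They were not matched on signal, and the shares per chromosome after cyclic loess are not given here. Since the share of gains depended on signal and on scaling, the uneven spread cannot be told apart from a signal-dependent shift. The median deviation of strong regions also varied by chromosome within the libraries. Across the 19 chromosomes, Spearman's rho of this deviation with the share of gained loci was 0.75, 0.76 and 0.52 in antibody replicates 1, 2 and 3 and 0.21, -0.80 and -0.78 in isotype replicates 1, 2 and 3. The calls come from the same values and chromosomes are not independent replicates, so this is a description.

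Inside the loci of 5 or more regions, regions that were not called mostly had the sign of their locus. In the authors' deposited table the log2 fold change was below 0 at 89.8% of 1910 such regions in lost loci, against 58.8% of uncalled regions outside these loci at the same mix of signal classes. It was above 0 at 91.5% of 248 such regions in gained loci, against 49.2% outside, in the authors' deposited table. The lost loci had a median length of 31.9 kb and the gained loci 27.1 kb.

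Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave as many changed regions as the real 12801, and the highest of the other 9 gave 0 by limma. At an unadjusted p of 0.05 the other splits gave 4651 to 11963 regions and the real split 41366. With 10 splits the share cannot fall below 0.1, so this test is too small to exclude chance.

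The first pattern weighed is the low signal of isotype replicate 2 on chromosome X. This library lay below the other 5 in 100% of the 787 strong X regions and in 8.40% of strong autosomal regions, which is consistent with reads of this chromosome being absent from its values. A single X copy against a pair in the other mice would lower the signal by at most 1 on the log2 scale, and the median deficit was -2.57 (quartiles -3.01 and -2.05) even on a shrunk scale, which argues against it. The median log2 fold change of strong regions in the authors' deposited table was 0.63 higher on X than on autosomes, close to the 0.58 (log2 of 3 over 2) that 1 of 3 isotype libraries at 0 would give. Whether the low signal set the gains on X cannot be told apart from a true gain at some of them, since 44% of the 75 calls were also made without that library.

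The second pattern is the excess of gains among weak and of losses among strong autosomal regions. Higher background in some antibody libraries remains a candidate explanation: in the weakest class antibody replicate 3 lay 0.009 below the highest isotype library (a difference of -0.009), and antibody replicates 1 and 2 lay above all isotype libraries. The strong end was uneven too, with antibody replicates 1 and 2 at 7.52 in class 5, and antibody replicate 3 at 7.60, above isotype replicate 3 at 7.59. A signal-dependent shift between libraries as the whole cause of the gains among weak regions stays open. After cyclic loess gains were 60.6% of the calls there, and the bound set beforehand was 60%. The Wilson 95% interval of 58.7 to 62.4% treats called regions as independent and holds no variation between mice. Over all regions gains were 57.4% of calls after cyclic loess. The bound took no account of that share, so it cannot decide the question. Most of the contrast between weak and strong regions went under the same correction. Gains were 69.5% of weak and 43.6% of strong calls before it, and 60.6% and 56.3% after it. However, cyclic loess would also remove a true effect that follows signal.

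The third pattern is that lost regions lay in larger loci than gained ones. Matching on the denser surroundings of lost regions removed most of it but not all, and matching on their stronger signal removed little. The locus of a lost region held 2.26 more regions than that of a gained region. The excess was 2.21 when matched on signal alone and 0.89 when matched on neighbours within 20 kb alone. It was 0.82 when matched on both (95% interval 0.52 to 1.15), and 0.72 when also matched on regions within 100 kb (0.42 to 0.94). No single library carried the unmatched gap in regions per locus. Losses exceeded gains by 0.198, 0.286 and 0.377 regions per locus without antibody replicate 1, 2 or 3. Without isotype replicate 1, 2 or 3 the excess was 0.144, 0.209 and 0.288 (0.496 with all 6 libraries). Each 95% bootstrap interval lay above 0, but these intervals resample chromosomes and hold no variation between mice. Matched sizes with a library left out are not given here. With a difference of at least 1 required on the shrunk scale, the gap was 0.04 and its interval included 0 (-0.072 to 0.211). Uneven shares of another cell type among the isotype libraries stay open, as the most common order of those libraries held in 39.4% of the 221 lost loci of 5 or more regions, between the bounds of 25% and 50% set beforehand, and no marker genes could be read. The share of neighbours called the same way was lower for losses than for gains when matched on signal and neighbours (95% interval of the difference -5.32 to -0.739 percentage points). Matched on neighbours alone, the interval included 0 (-4.69 to 0.086). The larger lost loci are therefore not shown to come from a stronger tendency to spread.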
